A study of Rattus norvegicus with 2 samples.

How the data were processed

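Total RNA from small mesenteric arteries was extracted with TRIzol and cleaned on RNeasy columns, per the labels, and pooled over 20 rats in each of 2 groups, sham operation and partial portal vein ligation. The file headers name the array as RG_U34A for both pools, with 1 chip lot, fluidics module 2 for the sham array and 1 for the portal hypertensive array. The amount of labelled cRNA is noted there, with a question mark, as 17 µg for the sham array and 12.5 µg for the portal hypertensive array. Each module and amount belonged to 1 group, so they cannot be told apart from the operation.

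The deposited values are 1 linear signal intensity per probe set and array, and the software, scaling target and background correction that the authors used to make them are not given in the sources used here. The means of the 2 columns after leaving out the lowest and highest 2% of values were 2504.33 and 2504.38, so the values had already been scaled to a common level and were used as deposited. The median intensity was 557 in the sham pool and 525.7 in the portal hypertensive pool, and the highest was 116259 and 133799. The deposited table used here holds no detection calls. Therefore the 40th percentile of all values of both arrays without control probe sets, 330.9, served as a floor, and lower values were set to it before log2 was taken. A probe set above the floor on both arrays was called measured (4960), on 1 array bounded (567) and on neither below the floor (3213). Because the floor compresses low signals, ratios of bounded probe sets are lower limits of the change.

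Probe sets were named from the platform annotation, in which 7018 had 1 gene symbol, 308 had several and 1473 had none, and the last 2 kinds name no gene here. Looking up gene identifiers in a RefSeq gene table of the rat assembly GRCr8 changed 0 symbols. No coordinates are given because no genome build is named for the array. The 7018 probe sets name 4737 genes, of which 3351 had a value and 3050 had a probe set measured on both arrays. The value of a gene was the median log2 ratio of portal hypertensive over sham over its probe sets with at least 1 array above the floor. Levels and ratios printed for a named gene are over its probe sets measured on both arrays, unless a single probe set is described. For 386 of 882 genes with several probe sets, the probe sets did not all go the same way.

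With 1 array per group no test was possible. Probe sets and genes were counted at a threshold of 2-fold. For 18 gene lists and 15 cell type marker lists, the median over members with a value was given with its order-statistic 95% interval, the members at least 1.5-fold apart, and the percentile of the median among 10000 random gene lists of the same size, drawn within 10 bins of mean level. A list below percentile 2.5 or above 97.5 was said to stand apart. The lists were smooth muscle contractile apparatus, vasoconstrictor receptors with renin-angiotensin and endothelin components, receptor coupling and kinases, nitric oxide and cyclic GMP, other vasodilator pathways, ion channels and pumps, extracellular matrix, growth factors and angiogenesis, cell cycle, immediate-early genes, heat shock and chaperones, inflammation, antioxidant defence, mitochondrial energy metabolism, glycolysis, ribosomal proteins, circadian clock and glucocorticoid response. Markers covered endothelium, smooth muscle and pericytes, fibroblasts, adipocytes, mast cells, macrophages, antigen presentation, lymphocytes, erythrocytes, nerve, pancreas, intestinal epithelium, mesothelium, skeletal and cardiac muscle, and hepatocytes.

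Named genes were the 12 with the highest and the 12 with the lowest ratio among genes whose probe sets all went the same way, with at least 1 probe set measured on both arrays and a mean level at or above the median of measured genes. Added to them were up to 4 bounded genes in each direction with the highest bound, up to 4 measured members of each list with the largest absolute ratio, and genes classically studied in portal hypertension whatever their values (Nos1, Nos2, Nos3, Cav1, Gch1, Adra1a, Adra1b, Adra1d, Agtr1a, Avpr1a, Ednra, Ednrb). In the clock list Per2, Nr1d1, Tef, Hlf and Bhlhe40 were named in addition, so that all 9 members with a value appear. Fasn, Scd2, Idh1, Acaca and Slc25a1 were added after their values were seen, and so was a set of 90 genes outside the ribosomal list whose levels lay in the central 50% of those of the ribosomal genes. The lists, the floor, the thresholds, the rest of this rule and the alternative settings were chosen before the data were examined.

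Control probe sets were set apart from all counts. The 9 spike-in probe sets had a mean log2 ratio of 0.28 (SD 0.28, from -0.07 to 0.88), with 8 above 0. The signal of the 3' probe set over the 5' probe set, a sign of RNA integrity and labelling, was 2.05 and 1.79 for beta-actin and 1.83 and 1.85 for GAPDH in the sham and portal hypertensive pools. Across measured probe sets the log2 intensities of the arrays correlated with r = 0.984, a value across probe sets, which are not independent replicates.

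The computation was tested on simulated data. In 3274 genes of a simulated array pair with technical scatter, 50 genes each were changed 1.5-fold, 2-fold, 3-fold and 4-fold, and their median estimates were 1.47, 2.03, 3.05 and 4.08. Of these, 8%, 56%, 98% and 98% passed the 2-fold threshold, against 0.13% of unchanged genes. These rates hold for the simulated genes and scatter and need not hold for genes near the floor. On the real arrays, the scatter of probe sets around their gene's mean reached 2-fold for 0.67% of 1801 probe sets. Among 223 probe sets at low signal it did so for 3.14%, while 2.69% of their ratios reached 2-fold. Of 1000 unchanged lists of 20 genes 5.9% stood apart, and of 50 lists shifted by 0.3 on the log2 scale 100% did.

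Alternatives changed the fold threshold to 1.5 or 3, centred the ratios on their median, applied quantile normalization, removed a loess trend of ratio on level (span 0.3), moved the floor to the 20th or 60th percentile, took the probe set with the highest level per gene, left out probe sets with suffixes for shared or reduced probes, drew random lists without matching, or kept only members measured on both arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.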

Results

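Gene expression was measured in small mesenteric arteries, the muscular vessels that set the blood supply of the intestine. The arteries came from rats with prehepatic portal hypertension and from sham-operated control rats. Portal hypertension had been produced by tying the portal vein partly shut before it enters the liver, which raises the pressure in the veins that drain the gut. Each group was represented by 1 pool of total RNA from 20 rats, and each pool was read on 1 Affymetrix RG_U34A array, a rat array with 8799 probe sets. There were no replicates, so every difference compares 2 pools and has no p-value or standard error, and the number of arrays limits the precision. The arrays were alike in overall signal. Of the 8740 probe sets that are not controls, 60.6% in the sham pool and 59.4% in the portal hypertensive pool lay above the floor of 330.9 intensity units. The floor is the 40th percentile of both arrays together, so the share above it over both was fixed in advance and is no detection rate. On both arrays, 4960 probe sets lay above it.

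The comparison asked which mRNAs of the mesenteric artery differ between portal hypertensive and sham-operated rats. Several genes of fatty acid synthesis and fat storage were higher in the portal hypertensive pool, led by Scd, the desaturase that makes monounsaturated fatty acids, at 2.63 times its sham level. Output genes of the circadian clock such as Dbp and Nr1d2 were higher and the clock activator Bmal1 was lower. The mast cell proteases Cma1 and Cpa3, the matrix protein gene Postn and several macrophage genes were also higher. The list of smooth muscle contractile genes had a slightly lower median, which lay within the central 95% of random lists under 4 of 9 alternative settings, and single genes such as Ptms and Rara were lower by more than 2-fold.

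Most of the transcriptome differed little between the pools. Across the 4960 probe sets measured on both arrays, the log2 ratio of portal hypertensive over sham had a median of -0.02 and an SD of 0.35, and 98.6% of ratios lay within 2-fold. At a threshold of 2-fold, 22 probe sets were higher and 45 lower. After summary by gene, which also takes in probe sets above the floor in 1 pool only, 11 genes were higher and 26 lower. Genes above the floor in 1 pool only among them included Ccl5 and Msx1 on the higher side. On the lower side they included Gstm7, Cyp2c11, Kcnn1, Mtmr7 and Ncan. Other scalings moved this balance: 30 probe sets were higher and 36 lower after quantile normalization, and 30 were higher and 37 lower after a loess trend of the ratio on the level was removed, with 14 genes higher and 21 lower in the latter case. Ratios of different probe sets of the same gene scattered with an SD of 0.30 around the gene's mean (1801 probe sets of 789 genes), and a ratio of 1.5-fold marks the edge of the central 95% of a normal spread of that size. This scatter was wider at low signal, with an SD of 0.40, and it leaves out all differences between rats.

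Some of the enzymes that make fatty acids or supply their carbon and reducing power were among the genes with the highest ratios, while others differed little or were lower. Scd had a signal of 11225 in the sham pool and 29482 in the portal hypertensive pool, a log2 ratio of 1.39 on the probe set measured on both arrays. Acly, which makes cytosolic acetyl-CoA from citrate, had a log2 ratio of 1.08 over 2 probe sets, and Me1, the cytosolic malic enzyme that yields NADPH, 0.92 over 4 probe sets. Acsl1, which activates long-chain fatty acids, was higher on all 4 of its probe sets, with log2 ratios from 0.69 to 1.37. G0s2, an inhibitor of triglyceride breakdown, had a log2 ratio of 0.82, and Taldo1, an enzyme of the pentose phosphate pathway, 0.77. Fasn, the fatty acid synthase gene, had 0.51 and -0.11 on its 2 probe sets, which went opposite ways, Scd2 had 0.14 over 4 probe sets, Idh1 had 0.14, and Acaca, the acetyl-CoA carboxylase gene, was below the floor in both pools. Slc25a1, the mitochondrial carrier that exports citrate, was lower, with signals of 2100.5 and 557 and a log2 ratio of -1.91. These 5 genes were picked after their values were seen. The secreted lipid carriers Apoe and Rbp4 had log2 ratios of 0.97 over 2 probe sets and 0.78 over 3 probe sets.

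The fixed list of adipocyte genes, which holds Scd, Acly, Me1, Acsl1 and G0s2, was higher as a group. Of its 19 members with a value, 17 had a ratio above 0, and 5 were at least 1.5-fold higher and 0 at least 1.5-fold lower. The median log2 ratio was 0.34 (order-statistic 95% interval over genes 0.14 to 0.82), at percentile 100 of 10000 random lists of the same size and level. Fat cell genes that are not enzymes of fatty acid synthesis were higher too, Fabp4 with a log2 ratio of 0.51, Pparg with 0.56, Lpl with 0.34 and Cfd with 0.28, while Lep had -0.21 and Adrb3 -0.34. These 6 genes were picked from the list after their values were seen. The sham pool already gave a signal of 15433 for Fabp4 and 17028 for the brightest Lpl probe set.

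**Figure D1:**
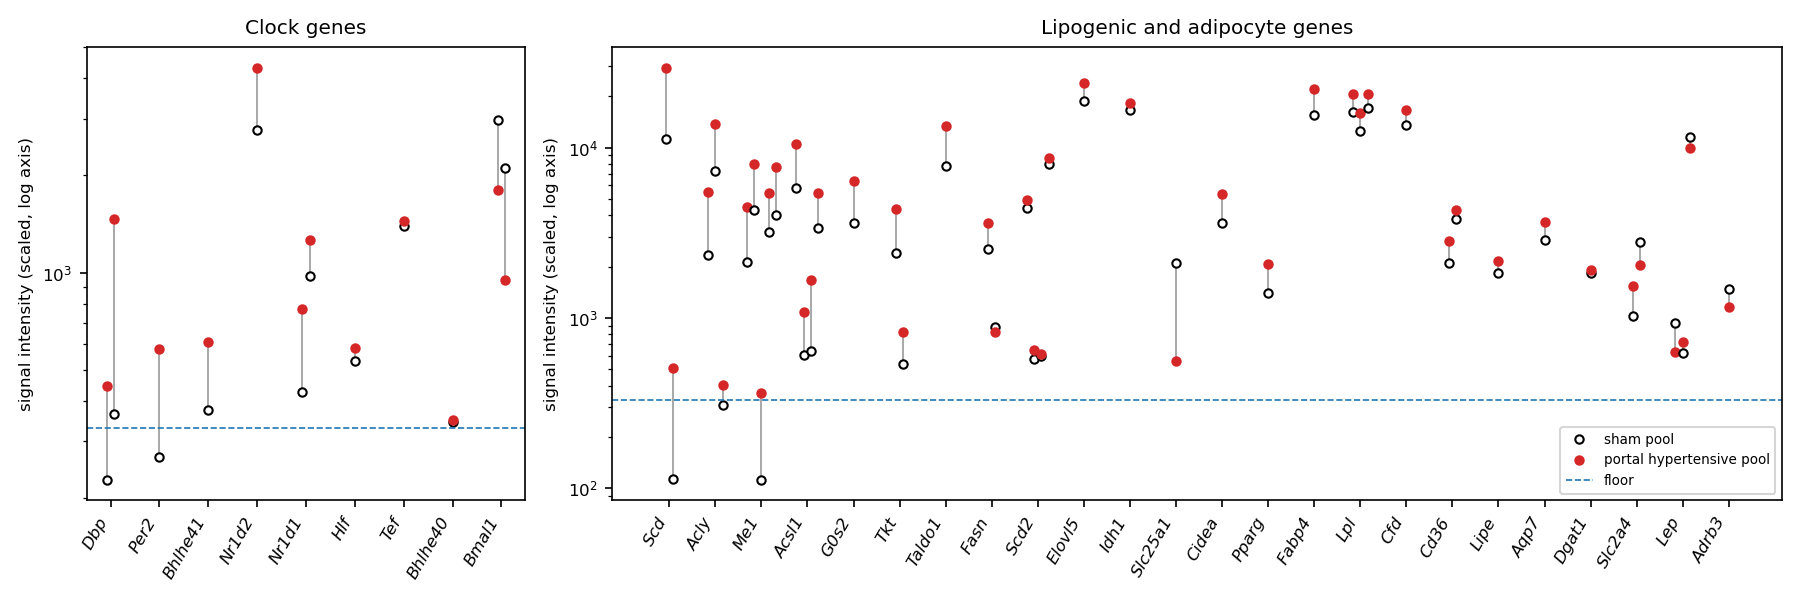
Signal intensity (log axis) of each probe set above the floor on at least 1 array, in the sham pool (open circles) and the portal hypertensive pool (filled circles), for clock genes on the left and lipogenic and adipocyte genes on the right. A line joins the values of a probe set and the dashed line is the floor of 330.9; both Bmal1 probe sets and that of Slc25a1 lie lower in the portal hypertensive pool, while Dbp, Scd, Acly, Me1 and Acsl1 lie higher on every probe set shown.

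The 8 output and repressor genes of the circadian clock with a value had ratios above 0, and Bmal1, the only activator gene with a value, was lower. Dbp, a transcription factor gene driven directly by the clock, had signals of 363.6 and 1461 in the sham and portal hypertensive pools on its measured probe set, a log2 ratio of 2.01, and on its other probe set it was below the floor in the sham pool. Nr1d2 and Nr1d1, which encode the repressors of Bmal1 transcription, had log2 ratios of 0.65 and 0.61, and Bhlhe41, another clock repressor gene, 0.70. Per2 was below the floor in the sham pool and reached 579.2 in the portal hypertensive pool. Bmal1, the activator that drives these genes, was lower on both of its probe sets, with log2 ratios of -0.72 and -1.16. Tef, Hlf and Bhlhe40 had log2 ratios of 0.06, 0.14 and 0.02, within the SD of 0.30 between probe sets of a gene. The list median was 0.61 (0.02 to 0.81, 9 genes) at percentile 99.99, with 5 genes at least 1.5-fold higher and 1 lower. The size for Dbp rested on a probe set near the floor in the sham pool, and its value over both probe sets was at least 1.22, because the other probe set gives only a lower limit.

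Markers of macrophages were higher as a list, while the call for fibroblast markers depended on the processing. Among 11 macrophage and myeloid genes, 8 had ratios above 0, including Fcgr2b, an inhibitory Fc receptor, with a log2 ratio of 0.92, the lysosomal protease gene Ctss with 0.50 and Aif1 with 0.46, while the pan-leukocyte gene Ptprc had -0.48 and -0.63 on 2 probe sets and was higher on the other, with signals of 353.2 and 704, so its direction was not settled. The macrophage median was 0.25 (-0.14 to 0.50) at percentile 99.78. Of 8 fibroblast and adventitia genes, 6 were above 0, with Thy1 at 0.58, Col3a1 at 0.32, Pdgfra at 0.22 and Col1a2 at 0.21, and their median was 0.20 (-0.17 to 0.58) at percentile 97.98. The fibroblast list no longer stood apart under 5 of 9 alternatives: quantile normalization (percentile 91.74), the loess (94.63), the floor at the 20th percentile (95.21), shared probe sets left out (89.47) and unmatched random lists (97.1). Postn, a matrix protein gene of connective tissue, had a signal of 8495 in the sham pool and 16140 in the portal hypertensive pool. The mast cell chymase gene Cma1 had a log2 ratio of 1.20 and the mast cell carboxypeptidase gene Cpa3 0.82, while the tryptase genes Tpsb2 and Tpsab1 had -0.37 and 0.10. The 6 mast cell genes with a value had a median of 0.13 (-0.37 to 1.20) at percentile 86.34, which was 99.945 with the floor at the 60th percentile and 99.82 with only members measured on both arrays.

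Most ribosomal protein genes were slightly higher. Of 40 genes, 32 had a ratio above 0 and 8 below it, and 0 reached 1.5-fold, with Rpl24 at a log2 ratio of 0.33, Rpl23 at 0.32 and Rpl19l4 at -0.43. Rpl3l had -0.27 on its measured probe set, and its other probe set went the opposite way. Their median was 0.16 (0.05 to 0.19) at percentile 99.98. After quantile normalization the list lay inside the range of random lists, at percentile 89.675.

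Genes of smooth muscle contraction had medians slightly below 0. Of 21 contractile apparatus genes, 14 had ratios below 0 and 0 reached 1.5-fold in either direction. Rock2, a kinase that sustains contraction, had a log2 ratio of -0.47, Acta2, the smooth muscle actin gene, -0.32, and Ppp1r12a, the targeting subunit of myosin phosphatase, -0.32, while Rhoa had 0.40. The list median was -0.10 (-0.14 to 0.07) at percentile 1.835, a call that ended after quantile normalization at 3.29, after the loess at 5.215, with shared probe sets left out at 18.74 and with unmatched random lists at 15.135. The markers of smooth muscle and pericytes had a median of -0.10 (-0.32 to 0.10) at percentile 4.39 (2.49 with the floor at the 60th percentile, 1.565 with the probe set of highest level and 2.08 with only members measured on both arrays), with Kcnmb1 at -0.68, Des at -0.28 and Tagln at 0.17. The Tagln value came to 0 after quantile normalization. Of 27 ion channel and pump genes, 19 were below 0, with a median of -0.14 (-0.32 to 0.04) at percentile 3.225, and at 2.225 after the loess, 0.52 with the floor at the 60th percentile and 1.975 with the probe set of highest level. Kcnmb1, the regulatory subunit of the large calcium-activated potassium channel, Pln, the brake of the sarcoplasmic calcium pump, with -0.48, and Kcna5, a voltage-gated potassium channel gene, with -0.43, were among the lower ones, while Kcnj11, a subunit of ATP-sensitive potassium channels, had 0.73 on its measured probe set, with signals of 360.4 and 596.8, and went the opposite way on its other one.

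Receptors for vasoconstrictors did not move together. Across 21 genes of vasoconstrictor receptors and of the renin-angiotensin and endothelin systems, 13 had ratios below 0 and 8 above 0, and the median was -0.18 (-0.32 to 0.13) at percentile 3.92. With the floor at the 20th percentile it turned to 0.02, at percentile 72.925, and with unmatched random lists the percentile was 1.73. The serotonin receptor genes Htr2a and Htr2b had log2 ratios of -0.91 and -0.45, and the neuropeptide Y receptor gene Npy1r -0.57, while Edn1, the endothelin precursor gene, had 0.62. Among receptors long studied in portal hypertension, Adra1d had a log2 ratio of -0.36, Adra1a -0.25 and Avpr1a 0.14. Agtr1a was higher on all 4 of its probe sets, with log2 ratios from 0.05 to 0.54. Adra1b was below the floor in both pools, and no probe set was named for Ednra or Ednrb.

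Neither nitric oxide genes nor genes of other vasodilator pathways stood apart as lists at the main settings, but the latter were at percentile 0.7 with the floor at the 20th percentile. The 22 genes of nitric oxide, cyclic GMP and natriuretic peptide signalling had a median of -0.03 (-0.19 to 0.13) at percentile 45.11, and the sign of this median turned with the scaling. Nos3, the endothelial nitric oxide synthase gene, gave log2 ratios of -0.78, -1.20 and 0.25 on its 3 measured probe sets, and its other 3 probe sets were below the floor in both pools, so its direction was not settled. The measured probe sets of Nos2 gave -0.14 and 0.43, and Nos1 was below the floor on all 3 of its probe sets. Cav1, which encodes a scaffold protein that binds endothelial nitric oxide synthase, had signals of 13739 and 12250, and Gch1, the first enzyme of tetrahydrobiopterin synthesis, had log2 ratios of -0.08 and 0.05. Qdpr, which regenerates tetrahydrobiopterin, had -1.04 on its measured probe set, with signals of 2185 and 1065, but its other probe set went the opposite way, Spr, another enzyme of that synthesis, had -0.32, and the arginine transporter gene Slc7a1 had 0.35. The 27 genes of other vasodilator pathways had a median of -0.09 (-0.27 to 0.10) at percentile 24.705, with the prostacyclin receptor gene Ptgir at -0.54, Prkar2b at -0.53 and Pde4a at -0.51, and Ephx2 at 0.50 on its measured probe set against the direction of its other one. For 23 genes of receptor coupling and kinases the median was -0.04 (-0.22 to 0.08) at percentile 44.805, with Itpr2 at -0.48, Prkcd at -0.34, Plcb4 at -0.33 and, on its measured probe set against the direction of its other one, Prkcb at 0.35. Its sign turned after the loess. Endothelial markers had a median of -0.10 (-0.29 to 0.39, 12 genes) at percentile 22.6, and their members went both ways, with Icam2 at -1.13, Aqp1 at 0.65 and Edn1 at 0.62. The endothelial median turned to 0.16 at percentile 96.54 with the floor at the 20th percentile and to 0.03 at percentile 67.29 with the floor at the 60th.

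The 12 genes with the lowest ratios under the rule for named genes were Bmal1 and 11 others, each of which rested on a single probe set. Ptms, which encodes the acidic nuclear protein parathymosin, had the lowest ratio of this ranking, with signals of 5633 in the sham pool and 1888 in the portal hypertensive pool. Rara, the retinoic acid receptor alpha gene, had signals of 4061 and 1402. Ate1, an arginyltransferase gene, Adk, the adenosine kinase gene, and Slc14a1, a urea transporter gene, had log2 ratios of -1.32, -1.19 and -1.18. Pcmtd2 had -1.15, Lig4, a DNA ligase of end joining, -0.99, Fam83f -0.99, Anxa4 -0.94, Nckap1 -0.94 and Trappc3 -0.93. Car5b, a mitochondrial carbonic anhydrase gene, with a log2 ratio of 0.85, completed the 12 highest genes.

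Some genes were above the floor in 1 pool only, which gives a bound that depends on the floor. The chemokine gene Ccl5 was at least 3.69-fold higher in the portal hypertensive pool, the homeobox gene Msx1 at least 2.07-fold, Ino80e at least 1.93-fold and Gys2, the liver-type glycogen synthase gene, at least 1.91-fold. The glutathione transferase gene Gstm7 was at least 4.03-fold lower, Cyp2c11, a steroid hydroxylase gene of the liver, at least 2.68-fold, Kcnn1, a small calcium-activated potassium channel gene, at least 2.25-fold and Mtmr7 at least 2.15-fold.

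**Figure D2:**
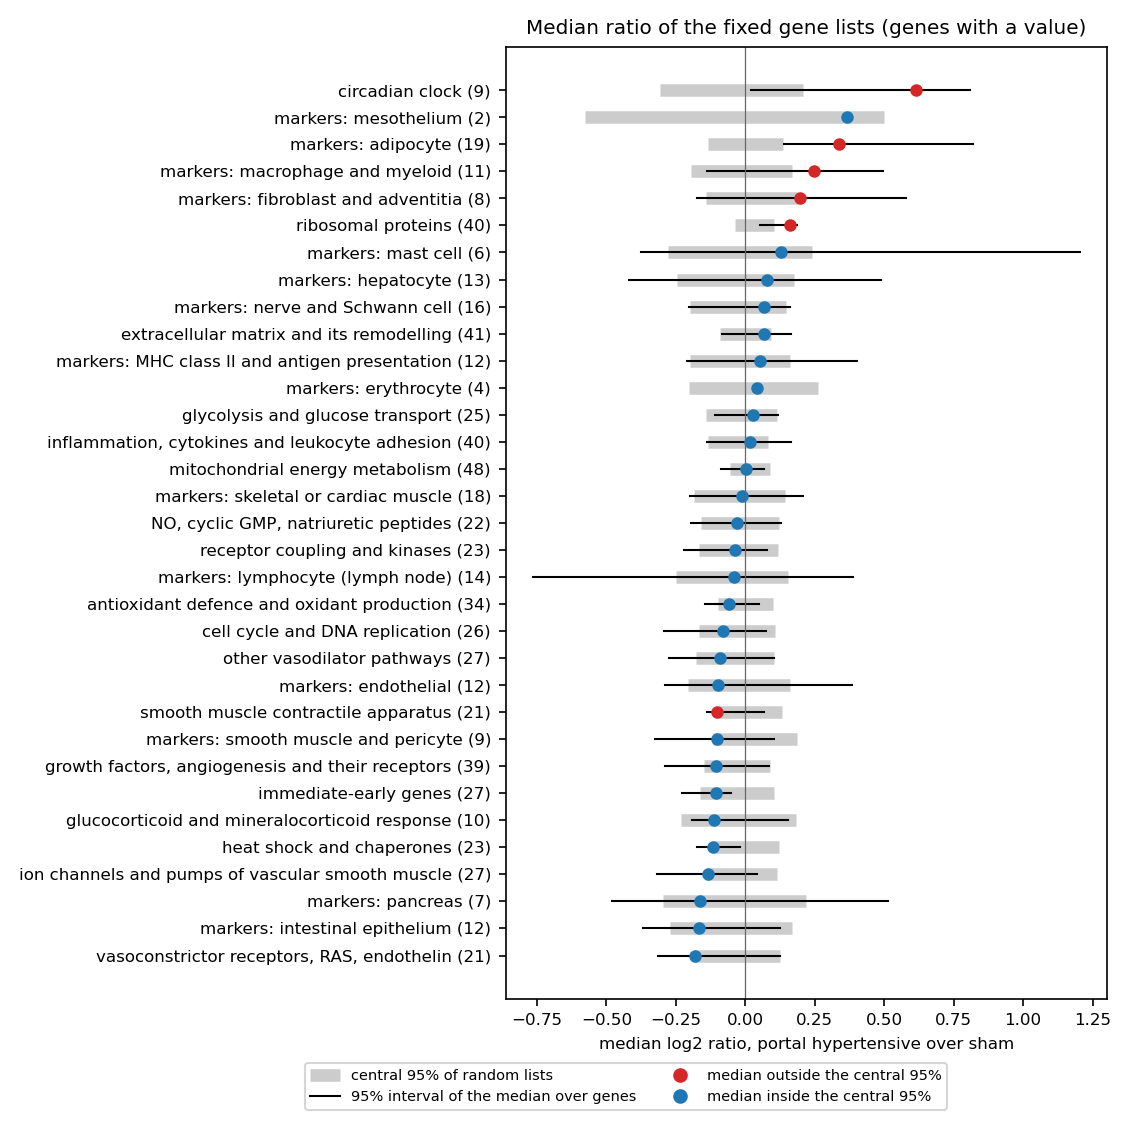
Median log2 ratio of portal hypertensive over sham for each of the 33 fixed lists (points), with the number of genes that had a value, the order-statistic 95% interval of the median over genes (lines, not drawn for lists too small to have one) and the central 95% of medians of 10000 random lists matched on level (grey bars). The clock, adipocyte, macrophage, fibroblast and ribosomal lists lie above their grey bar and the contractile list below it.

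Stress response genes were mostly below 0, although neither the heat shock nor the immediate-early list stood apart. Of 23 heat shock and chaperone genes, 18 had ratios below 0, while Hspa2 had 0.58. The median was -0.12 (-0.17 to -0.02) at percentile 2.7. Among genes of the endoplasmic reticulum stress response Hyou1 had a log2 ratio of -0.78, Ddit3 -0.60 and Hspa5 -0.47, with -0.81 and -0.13 on its probe sets. Other chaperones of the endoplasmic reticulum went both ways. Pdia4 and P4hb had 0.35 and 0.20, and Hsp90b1, Pdia3, Canx and Calr had -0.23, -0.12, -0.10 and -0.05. Of 27 immediate-early genes, 24 were below 0, with Klf6 at -0.71, Zfp36 at -0.53 and Nr4a2 at -0.51 on its measured probe set against Dusp6 at 0.72, and the median was -0.11 (-0.23 to -0.05) at percentile 12.885. The glucocorticoid response list had a median of -0.11 (-0.19 to 0.16, 10 genes) at percentile 20.85, with Cebpd at 0.13 and -0.85 on its 2 probe sets, Cebpb at 0.18, Dusp1 at -0.18 over its measured probe sets and Nr3c1 at 0.16. Another Dusp1 probe set, above the floor in the sham pool only, was at -1.62 or lower.

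Matrix, growth factor, proliferation and inflammation genes went both ways. Among 41 extracellular matrix genes the elastin gene Eln had a log2 ratio of 0.52 and Tnc 0.41, Bgn and Spp1 had -0.49 and -0.39, and the median was 0.07 (-0.08 to 0.17) at percentile 90.52, or 99.06 with the floor at the 60th percentile. Among 39 growth factor and angiogenesis genes Nrp1 had 0.52, Bdnf -0.65, Inhba -0.49 and Fgf2 -0.74 on its measured probe set against the direction of its other one, with a median of -0.10 (-0.29 to 0.08) at percentile 11.77. The cell cycle list had a median of -0.08 (-0.29 to 0.07, 26 genes) at percentile 24.52, with Cdk1 at -0.58, Ccng1 at -0.49, Ccnb1 at -0.48 and Ccnd2 at 0.20 and -1.01 on its 2 probe sets. The 40 genes of inflammation split evenly, 20 above and 20 below 0, with Ifngr1 at -0.65, Il1r2 at -0.60 and Il6r at 0.51, and a median of 0.02 (-0.14 to 0.16) at percentile 79.69, or 98.64 with the probe set of highest level. The antioxidant list had a median of -0.06 (-0.15 to 0.05, 34 genes) at percentile 11.84, with Mgst1 at 0.54, Gpx3 at -0.43, Xdh at 0.38 and Gsta4 at 0.37.

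Mitochondrial and glycolytic genes were centred near 0, and the sign of the mitochondrial median turned with the scaling. The 48 mitochondrial genes had a median of 0.00 (-0.09 to 0.07) at percentile 33.96, and the 4 that were at least 1.5-fold lower included Ndufs1, a complex I subunit gene, at -0.86, Acadvl at -0.66 and Acadl at -0.62, while Cpt2 had 0.37. The 25 genes of glycolysis and glucose transport had a median of 0.03 (-0.11 to 0.12) at percentile 75.7, with Pfkl at -0.82 and Pdk1 at 0.57. Pdk2 had -0.54 and Pfkfb1 0.50 on their measured probe sets, and the other probe set of each went the opposite way.

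Markers of other tissues and cells that the dissected arteries could carry did not stand apart as lists at the main settings. Under alternatives some did, lymphocyte markers at percentile 0.33 with the floor at the 20th percentile, hepatocyte markers at 99.62 with the floor at the 60th, and mesothelium markers at 98 with the probe set of highest level and at 98.08 with shared probe sets left out. Lymphocyte genes had a median of -0.04 (-0.76 to 0.39, 14 genes) at percentile 52.14, with Cd8b at -0.96, Cd247 at -0.75, Cd53 at 0.41 and Ptpn6 at 2.07 times its sham level. Genes of antigen presentation had a median of 0.05 (-0.21 to 0.40, 12 genes) at percentile 77.8, with Cd74 at 0.36, Psmb9 and RT1-DMb at 0.40 each and RT1-Da at 0.68, the RT1 values uncertain because RT1 genes have close copies. The haemoglobin gene Hbb had signals of 107955 and 122616, Hbb-b1 had a log2 ratio of 0.14, Alas2 -0.40 and Slc4a1 -0.11 and 0.01 on its 2 probe sets, and the 4 erythrocyte genes had a median of 0.04 at percentile 54.39, which turned below 0 after quantile normalization, as did the ratio of Hbb. Nerve and Schwann cell genes had a median of 0.07 (-0.20 to 0.16, 16 genes) at percentile 86.72, with Npy at -0.33, Syp at 0.25, Gap43 at -0.23 and Mag at -0.20. Pancreas genes had a median of -0.16 (-0.48 to 0.51, 7 genes) at percentile 16.35 and intestinal epithelium genes -0.17 (-0.37 to 0.13, 12 genes) at percentile 14.21, with Ctrc at -0.48, Rnase1 at 0.51, Ins1 at -0.39 and Ins2 at -0.25 in the former and Muc2 at -0.50, Apob at 0.49 and Anpep at 0.13 and 0.97 on its measured probe sets, against the direction of its other one, in the latter. The pair of mesothelium genes with a value, Krt18 at 0.54 and Efemp1 at 0.50 and -0.10 on its 2 probe sets, had a median of 0.37 at percentile 92.81. Skeletal and cardiac muscle genes had a median of -0.01 (-0.20 to 0.21, 18 genes) at percentile 54.71, with Casq1 at -0.45, Car3 at 0.36, Pygm at -0.31 and Tnnt3 at 0.26, and the sign of that median turned with the scaling. Hepatocyte genes had a median of 0.08 (-0.42 to 0.49, 13 genes) at percentile 86.235, with Hp at 0.57, Apob at 0.49 and Cps1 at -0.42.

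In all, 33 lists were compared with random lists, and 5 lay above the central 95% and 1 below it. By chance 1.65 would lie outside, if members of a list varied as independently as randomly drawn genes. Members of a list can vary together, and some lists share members, such as Acta2 in the contractile and smooth muscle marker lists. More lists than that could therefore lie outside without an effect of the operation. The percentiles describe these 2 arrays only. Other floors also turned the sign of the median of the nerve and inflammation lists (-0.04 and -0.06, 20th percentile) and of the lymphocyte and growth factor lists (0.16 and 0.03, 60th percentile). Leaving out shared probe sets turned the sign for the erythrocyte, glycolysis, mitochondrial, antioxidant and matrix lists (-0.23, -0.15, -0.03, 0.04 and -0.0049).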

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

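All alternative settings had been chosen before the data were examined. No paired analysis was possible because each group has 1 array. The clock, adipocyte and macrophage lists stood apart under each of the 9 alternatives run for lists, with percentiles of at least 99.465, 99.88 and 98.71 and medians of 0.37 to 0.67, 0.20 to 0.47 and 0.25 to 0.29. Counts depended on the threshold and on the floor by construction. Of the main 22 probe sets higher, 45 lower, 11 genes higher and 26 lower, a 1.5-fold threshold gave 154, 267, 105 and 169, a 3-fold threshold 3, 7, 1 and 3, a floor at the 20th percentile 132, 169, 88 and 97, and one at the 60th percentile 8, 14, 4 and 9. With the lower floor 9 of the 11 higher and 23 of the 26 lower genes were shared, and with the higher floor 2 and 8. Leaving out shared and reduced probe sets gave 12 higher and 18 lower genes, which shared 8 of the 11 and 12 of the 26. Lists changed sides of the percentile limits as follows, and the cause was not tested. With quantile normalization the percentile was 91.74 for fibroblast markers, 3.29 for the contractile apparatus and 89.675 for ribosomal proteins. With the loess it was 94.63 for fibroblast markers, 5.215 for the contractile apparatus and 2.225 for ion channels. With the floor at the 20th percentile it was 95.21 for fibroblast markers, 0.33 for lymphocyte markers and 0.7 for other vasodilator pathways, and the mesothelium median was 0.12. With the floor at the 60th percentile it was 2.49 for smooth muscle and pericyte markers, 99.945 for mast cell markers, 0.52 for ion channels, 99.06 for extracellular matrix and 99.62 for hepatocyte markers, whose median was 0.57. With the probe set of highest level it was 1.565 for smooth muscle and pericyte markers, 98 for mesothelium, 1.975 for ion channels and 98.64 for inflammation. With shared probe sets left out it was 89.47 for fibroblast markers, 98.08 for mesothelium and 18.74 for the contractile apparatus, and the glycolysis median was -0.15. With unmatched random lists it was 97.1 for fibroblast markers, 15.135 for the contractile apparatus and 1.73 for vasoconstrictor receptors. With members measured on both arrays it was 2.08 for smooth muscle and pericyte markers and 99.82 for mast cell markers. The signs of list medians also turned for glycolysis (-0.01 with the floor at the 20th percentile, -0.05 with the probe set of highest level), receptor coupling (0.01 with the latter) and lymphocyte markers (0.08 with the latter, 0.10 with members measured on both arrays). Over all lists and settings 271 percentiles kept their side, 16 newly stood apart and 10 no longer did. Over all pairs of named gene and setting, 936 ratios moved by less than the spread between probe sets and 69 by more. Named genes without a value under a setting were not counted. With the floor at the 20th percentile 135 moved by less and 19 by more. With the floor at the 60th these were 101 and 19, and with shared probe sets left out 103 and 12. Signal over background limits genes near the floor most, such as Dbp, whose log2 ratio was 2.01 with the probe set of highest level, and only a lower limit of 0.43 was left without shared probe sets, on a probe set below the floor in the sham pool.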

Other observations

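All tests of explanations in this part were chosen after the result was seen, except the loess test of an intensity-dependent bias in the ribosomal list, and the genes of the next paragraph were chosen after their values were seen.

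Further genes with large ratios or bounds fell outside the naming rule. Slc25a1, the mitochondrial carrier that exports citrate for fatty acid synthesis, had the lowest log2 ratio of any gene measured on both arrays, -1.91, with signals of 2100.5 in the sham pool and 557 in the portal hypertensive pool, opposite to Acly, which uses that citrate. Tkt, an enzyme of the pentose phosphate pathway like Taldo1, was higher on both probe sets, with log2 ratios of 0.86 and 0.63. Fabp5, a fatty acid binding protein gene, had a log2 ratio of 0.70 and Psat1, an enzyme of serine synthesis, 0.76 over its measured probe sets. Mcpt1l1, a gene related to mast cell proteases, had 0.71 over 2 probe sets and signals of 10032 and 15097, uncertain because such genes have close copies. The T cell gene Cd3d and the B cell gene Cd79b were above the floor in the sham pool only, which puts them at least 1.92-fold and 1.70-fold lower in the portal hypertensive pool.

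With the sign of Bmal1 turned, the mean log2 ratio of the 9 clock genes was 0.57, and the central 95% of random lists matched on level ended at 0.21. This mean adds no support, because the list had already stood apart and the direction of Bmal1 was known. More fat in the portal hypertensive pool would dilute the genes of the artery wall. The lower bound of the median was -0.14 for the contractile genes and -0.32 for both the smooth muscle markers and the ion channel list. Bmal1, at -0.72 and -1.16, was lower than dilution of that size would give. It is 1 gene, however, and Kcnmb1, a smooth muscle marker, reached -0.68, so more fat is not excluded for Bmal1. For the output genes more fat stays open too. The 14 adipocyte genes outside the lipogenic set, which include Acsl1 and G0s2, had an upper bound of the median of 0.57. That lies below the output median of 0.63 but inside its interval of 0.02 to 1.22. A different clock phase stays open, and the directions of the genes cannot test it, because they were known before the prediction was written. All 9 genes lay on the side of their group, activator or output, with Bmal1 opposite to Dbp, Per2 and Nr1d1. The prediction itself named neither Tef nor Hlf. Bmal1 was the only activator with a value. Tef, Hlf and Bhlhe40, at 0.06, 0.14 and 0.02, lay within the SD of 0.30 between probe sets of a gene. The labels give no hour of tissue collection, so a different hour and an effect of portal hypertension on the vessel clock cannot be told apart.

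The amount of perivascular fat left on the vessels was not told apart from a change of fat cell metabolism for the higher lipogenic and adipocyte genes. The 14 adipocyte genes that are not lipogenic enzymes had a median of 0.32 (0.06 to 0.57), with 12 above 0, and the 10 lipogenic genes 0.56 (0.14 to 0.93), with 9 above 0. The set of 14 held Acsl1 and G0s2, with log2 ratios of 0.86 and 0.82, both among the 12 highest genes. Its median is therefore no clean measure of the amount of fat. Both sets were drawn up after the list medians had been seen. The lipogenic set also held Taldo1, among the 12 highest genes, and Tkt, named after its values were seen. Neither is in the fixed adipocyte list, so the higher lipogenic median is no evidence of a larger change in that set. Both explanations stay open.

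The slightly higher ribosomal list could come from array bias or from labelling. The 9 spike-in probe sets had a mean log2 ratio of 0.28 (SD 0.28), with 8 above 0. That mean exceeds the medians of the ribosomal, fibroblast and macrophage lists, 0.16, 0.20 and 0.25. Spike-ins are not mRNA of the arteries, however. The noted amounts of cRNA also differed, 17 µg for the sham array and 12.5 µg for the portal hypertensive array. The spike-in mean therefore cannot tell whether a bias raised these lists. Removing a loess trend brought the ribosomal median from 0.16 to 0.083 and left the list apart at percentile 98.86. This result had been set beforehand to speak against an intensity bias. Judged afterwards, that limit ignored the spread, since the interval of the median after the loess, -0.01 to 0.12, reached below 0, and 90 other genes of the same level had been higher too, with a median of 0.06 (0.02 to 0.09) that the loess brought to 0.01, so bias stays open. Short mitochondrial subunit mRNAs, 23 in all, had a median of 0.02 with an upper bound of 0.086, above the lower bound of 0.05 of the ribosomal list, so labelling of short transcripts cannot be told apart from a biological difference either.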
